A study of Mus musculus with 4 samples.

How the data were processed

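The samples were 4 single-cell RNA libraries of mouse Ter119+CD44+ early erythroblasts, 1 per combination of tissue (bone marrow, spleen) and Dendra2 label (mito-, mito+), made with the 10x Genomics 3' v3.1 chemistry. The submitters' notes name Cell Ranger 6.0.0, Seurat and the genome build mm10, without the role of each. The authors deposited 2 matrices of UMI counts, each with 2 libraries, told apart by a barcode suffix. Each matrix held 32285 features. The deposited barcodes had at least 500 UMIs, at least 100 genes and under 10% mitochondrial UMIs, as the values show; no cell filter is stated. The authors also deposited 1 table per matrix with fold changes in log2, given as the difference of log2 mean counts per 10000 plus 1, shares of barcodes with a UMI, and p values (unit p_value), the adjusted ones being multiplied by the number of features.

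The suffixes were read from the authors' deposited tables: with suffix 2 as the first-named library, the share of barcodes with a UMI was within 0.001 and the fold within 0.01 for 15249 of 15249 genes of the first table and for 14537 of 14537 of the second; with the suffixes swapped, 1494 and 1701 shares matched. No label ties Y1, Y2, Y3 or Y4 to a titled sample, so libraries entered no group of the study and were compared only within a matrix, as the deposited tables pair them. Barcode sequences found in both libraries of a matrix numbered 0 and 5.

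Lists of genes, cell type markers, alternatives and the rule for named genes were chosen before the data were examined. The rule took, from each list, members with at least 50 CPM in 1 library and the largest and smallest ratios; the 10 highest and 10 lowest genes with at least 50 CPM in 1 library and 20 UMIs over both, without gene models named Gm or ending in Rik; the 5 largest folds each way in the authors' tables; and a fixed set that included Cd47, Thbs1, Tfrc, Cd44, Kit, Adgre1, Vcam1, Siglec1, Alas2 and Hmox1. Of 30 lists, the results of those not described in the results are given among the other observations.

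Counts were summed per library and scaled to CPM by the library total, with exact Poisson intervals. Ratios of CPM carry exact conditional binomial intervals; the all-gene median subtracted from them is treated as fixed. A gene was measured with at least 10 UMIs over both libraries of a matrix. A library at 0 was set to 3 counts for the ratio, and such ratios are bounds. The choice to report ratios relative to the median of all measured genes was made after the data were seen, because globin shares differ between libraries. The median of each list was placed among 10000 random lists of the same size drawn within 20 bins of mean expression; the interval of a list median is an order-statistic interval over its members, which are not independent. Values outside the percentiles 2.5 to 97.5 are treated as outside the range of random lists, which describes the libraries and is no test between samples.

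Cells were clustered in each matrix separately with scanpy 1.11.5: 10000 counts per cell, log values, 2000 variable genes, 30 components, an exact search for 15 neighbours, and Leiden at resolution 0.5. Clusters were named by the fixed markers. The thresholds of naming were set after the data were seen: a marker counted at 50 CPM and 1.5-fold, with 10 CPM added to both sides, and at least 3 markers were needed. A cluster also stayed unnamed where another class had markers among its top 10 genes, as many as its own class or more. Clusters kept out of a class by these thresholds held 65.4% of Y1, 9.64% of Y2, 1.23% of Y3 and 10.2% of Y4 barcodes. Of 4 versions of the clustering that were looked at, the reported one is that fixed beforehand. Shares of barcodes carry exact (Clopper-Pearson) binomial intervals.

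Scrublet, through scanpy, called 8, 3, 1 and 0 barcodes doublets in Y1, Y2, Y3 and Y4. That is under 0.5% of barcodes in each library, so doublets were in effect not treated. With 1 library per group no test, no paired analysis and no leave-one-out was possible, since a library has no replicate. Alternatives were a cell filter (1000 UMIs, 500 genes), globin or mitochondrial genes left out of totals, median-of-ratios size factors, the mean of per-cell CPM, thinning to 2000 UMIs, other low-count filters, doublets left out, other resolutions, 20 components with 30 neighbours, and other thresholds for the authors' tables and the correlation. A gene filter, sub-clustering and the globin slope over barcodes chosen without globin were added after the data were seen.

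The ratios and intervals were tested on simulated data made from the real means and library sizes. The intervals held the true value for 96.3% of 10753 unchanged genes with the sizes of Y1 and Y2 and for 95.8% of 12118 with those of Y3 and Y4. Of 50 genes lowered to a log2 ratio of -1, 64% and 78% had intervals that left out 0. Of 40 unchanged lists, 97.5% stayed within the percentile bounds in each matrix, and a raised list of 20 genes reached percentile 100. The simulation holds counting error only, with no spread between animals. Its counts follow the model that the intervals assume, so coverage near the nominal level was built in. Both libraries shared the same composition apart from the changed genes, and no all-gene median was subtracted, so that step was not tested. Gene positions are from GENCODE M21. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.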

Results

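The series profiled single cells of wild-type mice treated with phenylhydrazine (PHZ), a drug that lyses red cells and so drives stress erythropoiesis. The mice were given macrophages whose mitochondria carried the fluorescent protein Dendra2, and 5 days later Ter119+CD44+ early erythroblasts of bone marrow and spleen were sorted by the presence of that label. The labels name 4 samples, 1 library each: bone marrow mito-, bone marrow mito+, spleen mito- and spleen mito+. The deposited count matrices hold 4 libraries coded Y1 to Y4, paired as Y1 with Y2 and Y3 with Y4, and no label ties a code to a sample. Values are therefore given by code, and no value below is a mito+ against mito- or a bone marrow against spleen comparison. There were no replicates, so no test was made. Intervals on counts, shares and ratios are 95% intervals that cover counting error only.

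Library Y1 held 1749 barcodes and 8781317 UMIs, Y2 664 barcodes and 4017545 UMIs, Y3 4212 barcodes and 24382978 UMIs, and Y4 3108 barcodes and 20621600 UMIs. The median UMI count per barcode was 4003, 3502, 5337 and 4056 in Y1, Y2, Y3 and Y4. The median number of genes was 616, 925, 236 and 242, and 469, 680, 112 and 147 with every barcode thinned to 2000 UMIs, which left out 132, 24, 555 and 392 shallower barcodes. Globin genes took 54.8% of UMIs in Y1, 34.8% in Y2, 70.7% in Y3 and 40.7% in Y4. The mitochondrial genome took 1.80%, 2.48%, 1.11% and 2.90% in the same order. A list of 14 neutrophil-lineage genes took 7.06% of UMIs in Y1, 9.11% in Y2, 0.00537% in Y3 and 0.487% in Y4.

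The cell makeup of the libraries bears on whether the sorted fractions held the gated erythroblasts. Erythroid-like clusters held 33.0% of Y1 barcodes (30.8 to 35.3) and 11.4% of Y2 barcodes (9.12 to 14.1), against 97.4% in Y3 (96.9 to 97.9) and 88.1% in Y4 (86.9 to 89.2). Late erythroid-like barcodes made up 27.1% of Y1, 8.73% of Y2, 77.5% of Y3 and 80.1% of Y4, and erythroblast-like barcodes 5.95%, 2.71%, 19.9% and 7.95%. These shares depended on the settings. With the cell filter, which kept 1123, 592, 777 and 597 barcodes, erythroid-like shares became 83.4%, 5.24%, 90.3% and 63.3%, late erythroid-like ones 76.7%, 2.36%, 38.7% and 17.8%, and erythroblast-like ones 6.77%, 2.87%, 46.7% and 19.8%. The erythroblast-like share was 8.57% of Y3 and 4.67% of Y4 with 20 components and 30 neighbours, and 3.77% of Y1 at resolution 1.0. In Y2, 78.9% of barcodes (75.6 to 82.0) lay in a neutrophil-lineage-like cluster, whose leading genes also included the antigen presentation genes Cd74 and H2-Aa. The name depended on the settings: no barcode of Y1 or Y2 had it at resolution 0.3, with 20 components and 30 neighbours or with the cell filter, where 88.6%, 88.7% and 94.8% of Y2 stayed unnamed. Its share of Y1 went from 1.60% to 37.6% at resolution 1.0 and 33.6% with sub-clustering. In Y1, 61.2% (58.9 to 63.5) lay in cluster 0, which had immunoglobulin and neutrophil genes among its leading genes and stayed unnamed. A cluster with many UMIs per barcode, led by Prtn3, Myb, Mpo and Cdk6 and also unnamed, held 1.23% of Y3 (0.923 to 1.62) and 10.2% of Y4 (9.19 to 11.4). At resolution 1.0 no Y4 barcode stayed unnamed, and 5.08% of Y4 was early erythroid-like and 5.15% neutrophil-lineage-like (0.926% and 0.309% of Y3). With the cell filter these shares were 25.8% and 24.1% of Y4, and 4.89% and 1.80% of Y3. A B/plasma-cell-like cluster held 1.33% of Y3 and 1.71% of Y4, but the name was lost at resolution 0.3, with 20 components and 30 neighbours, without Scrublet doublets and with the gene filter. In that cluster 57.1% of Y3 barcodes held an Igkc UMI (median depth 5808 UMIs; 43.6% thinned to 2000 UMIs) and 22.6% of Y4 barcodes (median depth 1907; 11.5% thinned). In the erythroblast-like cluster 5 of Y4 the share was 35.8% (median depth 5536; 15.7% thinned), so Igkc does not support the name in Y4. The sort for Ter119 and CD44 preceded these shares.

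With 1 library per group, a cluster that came mostly from 1 library may be that library and not a cell type. This applied to cluster 0 of Y1, to the neutrophil-lineage-like cluster of Y2, and to the main late erythroid-like clusters of Y3 (3037 barcodes, 24 in Y4) and Y4 (2289 barcodes, 2 in Y3).

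**Figure D1:**
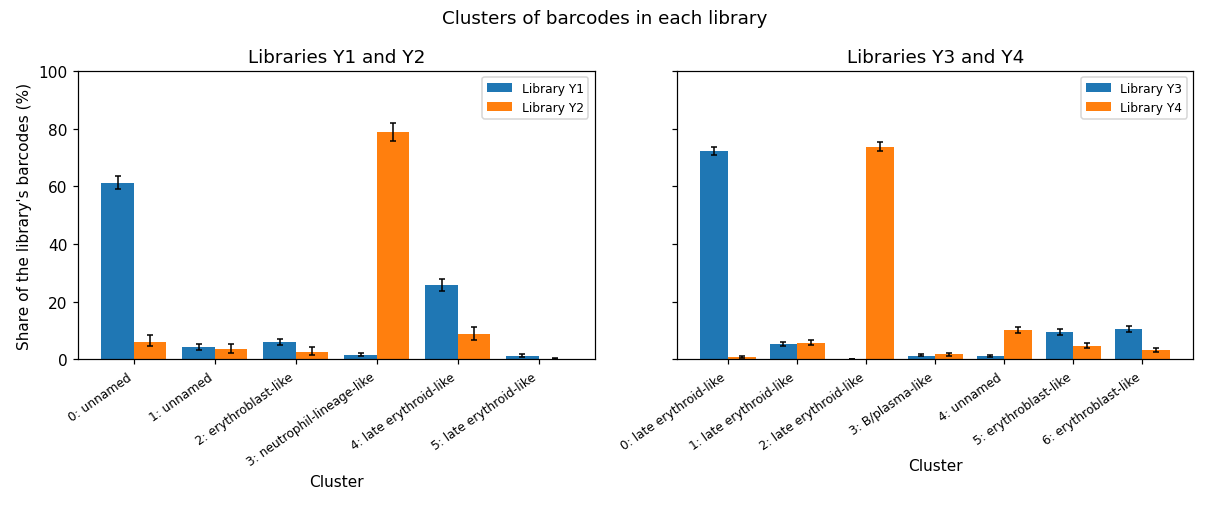
Share of each library's barcodes (percent, vertical axis) in each cluster (horizontal axis), for libraries Y1 and Y2 on the left and Y3 and Y4 on the right; bars are shares and error bars exact 95% binomial intervals. The largest cluster of Y1 holds 61.2% of its barcodes, that of Y2 78.9%, that of Y3 72.1% and that of Y4 73.6%, and in each matrix the largest cluster differs between the libraries.

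The first ratio compared library Y2 with Y1 over all barcodes. The median log2 ratio of CPM over 10953 measured genes was 0.78, and gene ratios are given relative to it. Genes of erythroid maturation were lower in Y2 than in Y1. All 16 measured genes of the late erythroid list lay below the all-gene median, each with its interval (list median -1.49; interval over members -1.54 to -1.41), and so did all 12 of the erythroid list, 11 by their intervals (-1.08). Among them were Slc4a1, the band 3 anion exchanger (-1.29; -1.38 to -1.20) and Tfrc, the transferrin receptor (-1.12; -1.26 to -0.99). Of 22 measured genes of haem synthesis and iron handling, 21 lay below the median, 20 by their intervals (list median -0.97; -1.11 to -0.74). Tfrc belongs to this list as well as to the erythroid and early erythroid lists. Alas2, the erythroid enzyme of the first step of haem synthesis, was at 1140.1 CPM (1117.9 to 1162.7) in Y1 and 594 CPM (570.3 to 618) in Y2, a relative log2 ratio of -1.72 (-1.78 to -1.65). Fech, whose enzyme inserts iron into protoporphyrin to form haem, was at -1.55, and the ferritin genes Fth1 and Ftl1 at -0.66 and -0.63.

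Mitochondrial gene groups lay nearer to the all-gene median in Y2 over Y1. The 13 protein genes of the mitochondrial genome had a list median of -0.33 (-0.45 to -0.03), at percentile 2.94 among 10000 random lists of like expression, with mt-Co1 at -0.47 and mt-Nd3 at 0.73. The 82 measured nuclear genes of the respiratory chain had a median of -0.02 (-0.07 to 0.05), percentile 66.1, and the 20 genes of the tricarboxylic acid cycle a median of 0.01, percentile 60.8. The mitophagy and autophagy list had a median of -0.45, percentile 0.06, with Bnip3l, the receptor used for mitochondrial clearance in reticulocytes, at -1.45 (-1.53 to -1.36), and Gabarap at -0.16. Ribosomal protein genes had a median of 0.16, with 70 of 81 above the all-gene median, and genes of the G2/M phase a median of -0.72, with all 30 below it.

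Neutrophil genes did not move one way between Y1 and Y2. The granule protein genes Ngp and Camp were lower in Y2, at -1.46 (-1.48 to -1.43) and -1.26 (-1.28 to -1.24), while the receptor genes Csf3r and Cxcr2 were higher, at 1.76 (1.60 to 1.92) and 1.63 (1.43 to 1.82). The neutrophil list's median of 0.29 (-1.18 to 0.72; percentile 99.8) became -0.07 with each cell weighted alike and -0.09 with barcodes thinned to 2000 UMIs. The genes with the largest ratios included Cd300ld (2.49), Cd3d (2.28), the cytokine gene Il1b (2.26) and Fos (2.07). The lowest were the immunoglobulin genes Igha (-7.96; -9.17 to -6.98), Jchain (-6.28) and Igkc (-5.68; -6.00 to -5.38), and the lowest 10 also included the basophil protease gene Prss34 (-2.67), Ube2o (-1.62) and the survival gene Bcl2l1 (-1.62). Igkc was at 678 CPM in Y1 and 22.7 CPM in Y2. In the unnamed cluster 0 of Y1, 79.8% of barcodes held an Igkc UMI, at 5.36 per barcode (median depth 3348). In the late erythroid-like cluster 4 of Y1 15.3% did (median depth 5794).

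Cd47, the cell surface ligand of SIRPα, was at 258 CPM (247 to 269) in Y1 and 326 CPM (309 to 344) in Y2, a relative log2 ratio of -0.44 (-0.54 to -0.34). Thbs1, which encodes the CD47 ligand thrombospondin-1, was at 9.34 CPM in Y1 and 36.8 CPM in Y2 and Cd44, one of the sort markers, at a relative log2 ratio of 0.76 (0.57 to 0.95). Of the macrophage genes used as sort markers for the injected cells, Adgre1 was at 2.73 CPM in Y1 and 10.5 CPM in Y2, Vcam1 at 14.1 and 16.4 CPM, and Siglec1 had 1 UMI in Y1 and 0 in Y2. Kit was at -0.49 (-0.95 to -0.04) and Hmox1 at -0.05 (-0.61 to 0.50).

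The second comparison kept the erythroid-like barcodes, 578 in Y1 and 76 in Y2, to lessen differences that come from cell makeup. It pooled stages, so a shift in their mix was not separated from differences within a stage. Over 6350 measured genes the median log2 ratio was 0.87. Nuclear genes of mitochondria lay above it: the respiratory chain had a list median of 0.50 (0.34 to 0.62) with 70 of 80 genes above, 35 by their intervals, and mitochondrial ribosomal proteins one of 0.67 (0.48 to 0.87) with 64 of 73 above. Mitochondrial chaperones and proteases had a median of 1.21 (0.25 to 2.09) with 11 of 12 above, led by Hspe1, the mitochondrial chaperonin 10 (2.16; 1.52 to 2.82), at 8.39 CPM in Y1 and 68.4 CPM in Y2. All 80 measured cytosolic ribosomal protein genes lay above the all-gene median (list median 0.62). These 4 lists stood at percentile 100 of random lists. The mitochondrial genome list was at -0.07 (-0.38 to 0.68; percentile 57.7), with mt-Nd1 at 0.92 and mt-Co1 at -0.38. The tricarboxylic acid cycle was at 0.52 (0.00 to 0.72; percentile 99.4) with 15 of 19 above. Late erythroid genes lay below, at -1.08 (-1.16 to -0.81), the mitophagy and autophagy list was at -0.92 (-1.16 to -0.52), and the haem and iron list at -0.41 (-0.99 to -0.10; percentile 5.76). Alas2 was at -1.23, Tfrc at -0.78 and Cd47 at -0.18 (-0.36 to 0.00). Cluster 4, late erythroid-like, held 452 of the Y1 and 58 of the Y2 barcodes used, and the erythroblast-like cluster 2 held 104 and 18. The late erythroid-like cluster 5 added 22 barcodes of Y1, of which Scrublet called 27.3% doublets, and 0 of Y2. The neutrophil list was at -0.61 (-1.77 to 0.39; percentile 0.84), with 6 of 14 genes above, Camp at -2.58 and Ngp at -2.33. In cluster 4 alone, Camp was at 1.05 UMIs per barcode in Y1 (median depth 5794) and 2.05 in Y2 (median depth 10574), or 0.331 and 0.431 when thinned. In the erythroblast-like cluster 2 of Y1 it was at 14.6 UMIs per barcode and S100a8 at 19.3 (median depth 4809; 1.44 and 3.32 when thinned), and the neutrophil list took 1.04% of UMIs there against 0.245% in Y2.

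Library Y4 was compared with Y3 in the same way. The median log2 ratio over 12318 measured genes was 1.55. Genes of erythroid maturation were lower relative to it in Y4: all 16 late erythroid genes (list median -2.06; -2.27 to -1.80), all 12 erythroid genes (-1.52) and 9 of 9 measured globin genes (-2.21) lay below by their intervals. Slc4a1 was at -2.63 (-2.67 to -2.59) and Tfrc at -1.99 (-2.06 to -1.92). Of 22 haem and iron genes 21 lay below, 20 by their intervals (-1.63; -1.99 to -1.25), with the mitochondrial iron importer gene Slc25a37 at -2.41. Alas2 was at 1757 CPM (1741 to 1774) in Y3 and 1096 CPM (1082 to 1111) in Y4, a relative log2 ratio of -2.23 (-2.25 to -2.21). The unnamed high-UMI cluster, 10.2% of Y4 barcodes, supplied 8916095 of the library's 20621600 UMIs, and with each barcode weighted alike the late erythroid list was at -0.68, globin at -0.50, the haem and iron list at -0.92 and Alas2 at -0.45. Thinned to 2000 UMIs per barcode, these were -0.91, -0.93, -1.01 and -0.99. All 30 genes of the G2/M phase lay below (-1.29), among them Mki67 at -1.99 and Cenpf at -2.07.

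Genes of early erythroid cells went both ways in Y4. The early erythroid list had a median of 0.75 (-1.15 to 0.87; percentile 100), with 9 of 12 genes above and 3 below by their intervals, Tfrc at -1.99 and Rhd at -1.82 among the latter, Cdk6 at 0.97 (0.85 to 1.08), Kit, the stem cell factor receptor, at 0.87 (0.65 to 1.09) and Mt2 at 0.76. The stem and progenitor list had a median of 1.60 (0.80 to 2.69) with 9 of 10 above. Glycolysis genes had a median of 0.75 (0.32 to 1.18; percentile 100) with 15 of 18 above, Pgam1 at 1.72 and Pkm at 1.48, although Bpgm, which makes 2,3-bisphosphoglycerate in red cells, was at -1.91. Mitochondrial ribosomal proteins had a median of 0.41 with 66 of 78 above, and mitochondrial chaperones and proteases one of 0.43 (-0.21 to 0.74; percentile 99.8) with 9 of 12 above and Hspd1 at 0.84. The nuclear respiratory chain list was at -0.06 (-0.17 to 0.07; percentile 88.2) and the mitochondrial genome list at -0.10 (-0.76 to 0.18; percentile 64.8), with mt-Nd1 at 0.32 and mt-Co1 at -0.76. The mitophagy and autophagy list was at -1.12 and the integrated stress response list at -1.15, with Ppp1r15a at -2.25, Eif2ak1, the haem-regulated eIF2α kinase gene, at -2.01, and Phgdh at 0.93. With each barcode weighted alike, the mitophagy and autophagy list was at -0.24, the integrated stress response list at -0.35, glycolysis at 1.51 and the stem and progenitor list at 3.23. Within erythroid-like barcodes, which leave out the unnamed cluster led by Prtn3, Myb, Mpo and Cdk6, the early erythroid list was at 0.99 (-0.26 to 1.29; percentile 100) with 9 of 12 above.

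The 10 highest genes in Y4 were Xist and granulocyte or basophil genes. All 14 neutrophil-lineage genes lay above the all-gene median by their intervals (list median 4.86; 4.17 to 6.03), with Elane, the neutrophil elastase gene, at 1.80 CPM (1.31 to 2.42) in Y3 and 659 CPM (648 to 669.7) in Y4. S100a9 was at 9.31 CPM in Y3 and 1171 CPM in Y4, a relative log2 ratio of 5.43 (5.24 to 5.62), and S100a8 at 5.13 (4.92 to 5.34). Prss34 had 0 UMIs in Y3 and 3348 in Y4. With Y3 set at a floor of 3 counts, its relative log2 ratio was at least 8.82. The second basophil protease gene, Mcpt8, was at 6.02 (5.04 to 7.24). Xist, the RNA of the inactive X chromosome, had 7 UMIs in Y3 and 3513 in Y4 (7.66; 6.62 to 8.98). The lowest genes were Iglc2 (-8.85), Igha (-8.08), Jchain (-7.81) and Igkc (-6.88; -6.97 to -6.78), with Cd74 (-3.39) and Ighm (-3.24), then Dmtn (-2.84), Arf5 (-2.65) and Sox6 (-2.64), a regulator of erythroid maturation. Igkc was at 725 UMIs per barcode in the B/plasma-cell-like cluster of Y3 and at 0.623 in that of Y4.

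Cd47 was at 326 CPM (319 to 334) in Y3 and 424 CPM (415 to 433) in Y4, a relative log2 ratio of -1.17 (-1.22 to -1.13). Thbs1 had 6 and 5 UMIs, so that no difference was detectable at this depth. Adgre1 was at 0.451 and 1.31 CPM, Vcam1 at 1.11 and 2.28 CPM, with relative log2 ratios of -0.01 and -0.51 that became 1.30 and 0.75 with each barcode weighted alike, and Siglec1 had no UMI in either library, against floors of 0.123 CPM in Y3 and 0.145 CPM in Y4. Cd44 was at 0.34 (0.14 to 0.54) and Hmox1 at -2.95 (-3.83 to -2.14) from 53 and 17 UMIs.

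Within erythroid-like barcodes, 4104 in Y3 and 2737 in Y4, the median log2 ratio over 10002 genes was 0.32. The late erythroid list was at -0.26 (-0.62 to -0.14; percentile 22.7) and globin at -0.37 (percentile 6.96), while the erythroid list was at -0.72 (-0.97 to -0.41) with 12 of 12 genes below by their intervals, and the haem and iron list at -0.43 (-0.77 to -0.06; percentile 0.6). Tfrc was at -0.98 (-1.07 to -0.89), Tal1 at -1.06, Cpox at -0.97, Cd47 at -0.56 (-0.62 to -0.49) and Alas2 at -0.30. All 30 genes of the G2/M phase lay below by their intervals (-0.63), and the 10 lowest genes included histone genes such as Hist2h2bb (-1.45) and Hist1h3c (-1.25), and Hemgn (-1.11). Glycolysis genes lay above (1.16; 0.30 to 1.73), with Gapdh at 0.94, as did mitochondrial ribosomal proteins (0.49), mitochondrial chaperones and proteases (0.66; -0.21 to 1.06; 9 of 12 above), with Hspe1 at 1.16 and Hspd1 at 1.13, the tricarboxylic acid cycle (0.29) and the nuclear respiratory chain (0.12; 0.05 to 0.25), each at a percentile above 99.8. The mitochondrial genome list was at 0.11 (-0.31 to 0.22; percentile 97.4). Late erythroid-like barcodes came mostly from cluster 0 in Y3 and cluster 2 in Y4, and erythroblast-like barcodes made up 839 of the Y3 and 247 of the Y4 barcodes used. The latter pooled 2 clusters. Cluster 5 (397 in Y3 and 148 in Y4) had histone and cycle genes among its leading genes. Cluster 6 (442 and 99) had Pcna but no histone gene among them, at median depths of 1019.5 and 758 UMIs. The neutrophil list was at 5.90 in these barcodes as well: S100a8 had 2.85 UMIs per barcode in cluster 2 of Y4 (median depth 3923 UMIs), where 92.4% of barcodes held one, and 0.0408 in cluster 0 of Y3 (median depth 5589), where 3.92% did. Thinned to 2000 UMIs, these shares were 75.4% and 1.36%. In the erythroblast-like cluster 5, a type that should lack the gene, 92.6% of Y4 barcodes held an S100a8 UMI at a median depth of 5536 UMIs (57.8% when thinned).

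**Figure D2:**
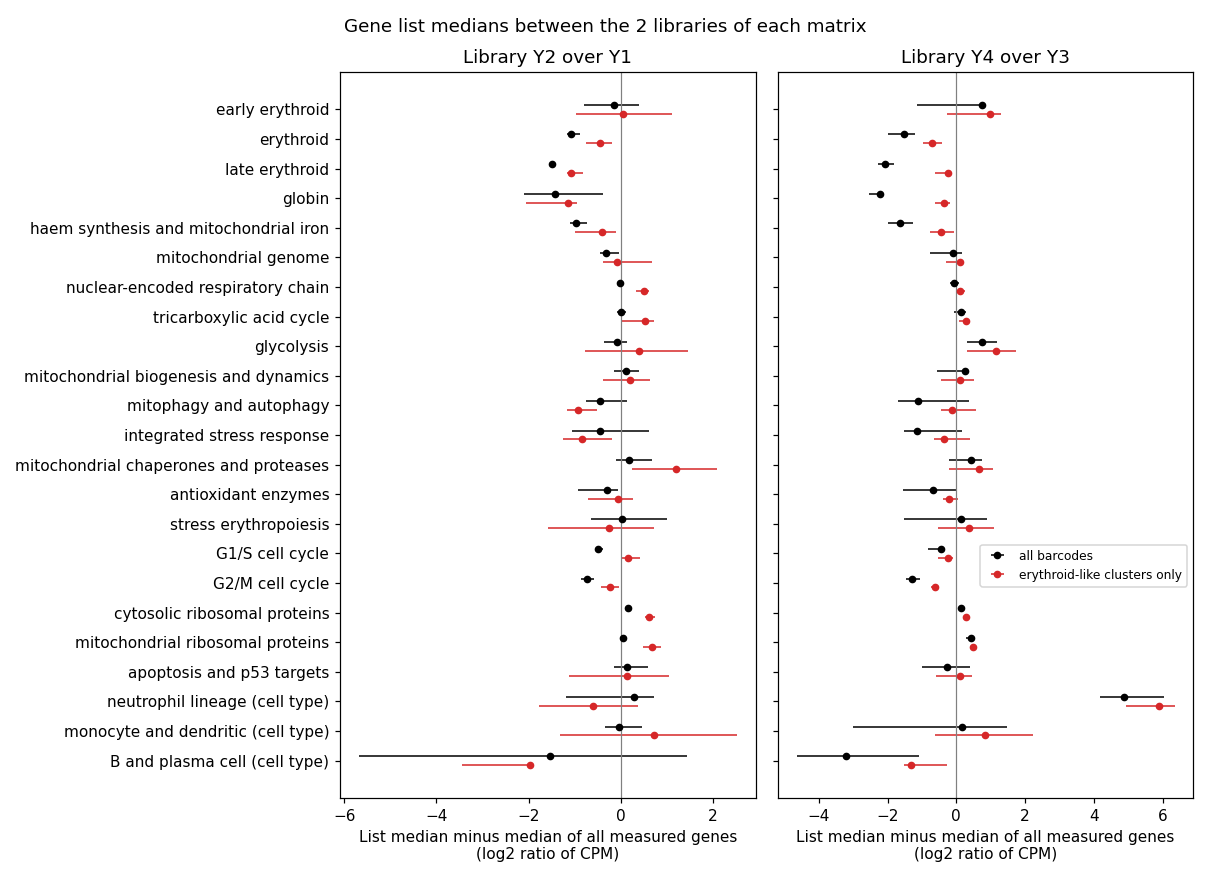
Medians of gene lists (rows of the vertical axis) in the log2 ratio of CPM between the libraries of each matrix, less the median of all measured genes (horizontal axis); black points are all barcodes, red points erythroid-like clusters only, and bars are order-statistic intervals over list members. Late erythroid genes lie at -1.49 for Y2 over Y1 and -2.06 for Y4 over Y3 in all barcodes, and at -1.08 and -0.26 within erythroid-like clusters; the neutrophil list lies at 4.86 for Y4 over Y3.

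Across 985 genes with at least 50 CPM in both matrices, the log2 ratio of Y2 over Y1 and that of Y4 over Y3 had a Pearson correlation of 0.603 and a Spearman correlation of 0.677. Within erythroid-like barcodes these were 0.0396 and 0.427 over 597 genes. Genes are not independent replicates, and no label says that the pairs carry the same contrast.

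In the authors' deposited table of Y2 against Y1, 2878 genes were higher and 47 lower at an adjusted p of 0.05, and 385 and 25 of these had an absolute log2 fold of at least 0.5. In the authors' deposited table of Y4 against Y3, 6113 were higher and 1278 lower, 126 and 31 with such a fold. Those p-values treat cells as replicates, and each compares 1 library with 1. For Y2 over Y1 the authors' deposited table gave the largest folds to S100a6 (1.78), Csf3r (1.71), Btg1 (1.58), Hist1h2ap (1.58) and Il1b (1.47), and the lowest to Igkc (-2.91), Igha (-2.16), Jchain (-1.48), Alas2 (-0.94) and Epb41 (-0.76). For Y4 over Y3 the authors' deposited table gave the largest to S100a9 (3.78), S100a8 (3.32), Camp (2.30), Ngp (2.06) and Elane (1.74), and the lowest to Igkc (-1.92), Igha (-1.13), Iglc2 (-1.05), Mki67 (-1.04) and Hemgn (-0.99). Cd47 had a log2 fold of 0.20 in the authors' deposited table of Y2 against Y1 (adjusted p 0.00336) and -0.31 in that of Y4 against Y3 (adjusted p 1). These folds are differences of log2 means per cell and are not relative to the all-gene median.

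On GRCm38 (mm10), the gene Alas2 (ENSMUSG00000025270) lies on chromosome X from 150547375 to 150570638, Cd47 (ENSMUSG00000055447) on chromosome 16 from 49800533 to 49915010, S100a9 (ENSMUSG00000056071) on chromosome 3 from 90692632 to 90695721, and the long noncoding RNA gene Xist (ENSMUSG00000086503) on chromosome X from 103460366 to 103483254.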

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

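Each result here is RNA of cells other than erythroid ones, or sex-linked RNA, above the limit that a count of 0 allows. The late erythroid-like Y4 barcodes that hold neutrophil RNA also enter the comparison within erythroid-like barcodes. Late erythroid-like barcodes of Y1 and Y2 hold such RNA too and enter theirs. The tests of free RNA in Y4, of doublets in a minority of barcodes, of material of 1 composition in some droplets, of neutrophil UMIs in late erythroid-like barcodes of Y1 and Y2, and of the globin slope over barcodes chosen without globin were chosen after the result was seen. No explanation by tissue or by mitochondrial label was tested, because the libraries cannot be tied to the groups.

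Neutrophil granule RNA was found in erythroid barcodes of library Y4: the neutrophil list took 0.269% of UMIs in its late erythroid-like barcodes. Doublets in a minority of barcodes do not explain this, since 99.6% of the 2490 barcodes (99.2 to 99.8) held an S100a8 or S100a9 UMI. Free RNA in the suspension may account for much of it, but its test cannot tell it from RNA held by each cell at a like level. Barcodes without such a UMI were 0.317 times as frequent as the Poisson chance at each barcode's depth (0.442% against 1.39%). An equal amount in each barcode would leave 0.0980% without one, so the observed share lay between these models. S100a8 stood at 2.85 UMIs per barcode in the late erythroid-like cluster 2, 3.15 in the erythroblast-like cluster 5 and 3.11 in the shallow erythroblast-like cluster 6. It was not even over all Y4 clusters, with 1.17 in the 24 late erythroid-like barcodes of cluster 0, 17.3 in the B/plasma-cell-like cluster 3 and 24.9 in the unnamed cluster 4. The planned test by Scrublet was void, because it called 0 barcodes in Y4 and so took away 0% of the share. RNA carried over from another library was not tested.

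In Y1, 61.2% of barcodes lay in the unnamed cluster of mixed globin and neutrophil RNA, and in Y2 78.9% lay in the neutrophil-lineage-like cluster. An Igkc UMI was held by 79.8% of the barcodes of the former and 11.5% of those of the latter. Globin took a median of 48.9% of UMIs per barcode in the former (quartiles 46.6 and 51.2) and 29.9% in the latter (28.1 and 32.3). The slope of log globin UMIs on log other UMIs was 1.04 in Y1 and 1.13 in Y2, which passes the planned limit of 0.5 against a fixed amount of free globin RNA in neutrophils. That test decides nothing, because clusters pick barcodes partly by their globin share. Over barcodes with the neutrophil list at 10% or more of UMIs outside globin, the slope was 0.413 in Y1 (0.337 to 0.488) and 0.802 in Y2 (0.730 to 0.874). With limits of 5% and 20% it was 0.259 and 0.477 in Y1, and 0.699 and 0.755 in Y2. These barcodes were not held to a single cluster. In Y1 they can include the deeper cluster 1, with globin at 7.40% of UMIs and the neutrophil list at 10.4%. The Y1 slopes may therefore mix populations, and a fixed amount stays open there. In Y2 the slopes argue only against an amount alike in shallow and deep barcodes. The test of free RNA in Y4 took such RNA to grow with barcode depth, which would raise the slope. Free globin RNA of that kind stays open in Y2 as well. A mixed pool in every droplet met its planned test, a slope between 0.8 and 1.2 in both libraries. It is excluded all the same by a value chosen afterwards, since late erythroid-like barcodes held at most 0.0432 times as many neutrophil UMIs per barcode as these clusters. Material of 1 composition in some droplets only, such as clumped debris, may be present, but these slopes do not settle it. In Y2 the slope of 0.802 lay between 0.8 and 1.2, as this material would need, while 0.699 and 0.755 lay below. In Y1 all 3 slopes lay below 0.5, over barcodes that may mix populations. Neutrophils that contain globin RNA in proportion to their own remain open and untested.

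Xist reached 170 CPM in Y4 against 0.287 CPM in Y3, 0.114 CPM in Y1 and 0 UMIs in Y2, and the unnamed high-UMI cluster, which held 3060 of the 3513 Xist UMIs, was 10.2% of Y4. A larger share of early cells does not explain the difference, since Xist CPM within that cluster was 529 times that of Y3 (94.8 to 20885), where it had 1 UMI. Nor do libraries of purely different sex, since the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together were only 1.54 times as high in that cluster of Y3 as in Y4. Library Y4 may hold cells of both sexes: of 92 barcodes with at least 3 Xist UMIs, 3.26% (0.678 to 9.23) held a Y-linked UMI, against 85.1% (79.8 to 89.5) of 222 barcodes without Xist, a ratio of 0.0383, at median depths of 25682 and 23503 UMIs and with Y-linked genes at 1.51 and 144 CPM. Whether these were different mice, donor-derived cells or a mixed library cannot be settled from the labels.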

How the results depend on the processing

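Tests of the gene filter and of sub-clustering were added after the data were seen. The haem and iron list (-0.97 for Y2 over Y1, -1.63 for Y4 over Y3) kept its sign under each alternative run; it was -1.15 and -0.92 with the mean of per-cell CPM, -1.01 for Y4 over Y3 when thinned, and -0.41 and -0.43 in erythroid-like clusters only. The nuclear respiratory chain list, near 0 (-0.02 and -0.06), was -0.14 and 0.10 with the mean of per-cell CPM, -0.091 for Y2 over Y1 when thinned, 0.50 and 0.12 in erythroid-like clusters only, and 0.11 for Y4 over Y3 without a low-count filter. For Y2 over Y1 the neutrophil list turned from 0.29 to -0.070 with the mean of per-cell CPM, -0.091 when thinned and -0.61 in erythroid-like clusters; the mast cell and basophil list turned from -0.61 to 0.54 with the mean of per-cell CPM and 0.90 when thinned, and the G1/S list from -0.48 to 0.15 in erythroid-like clusters. For Y4 over Y3 the megakaryocyte list turned from -0.94 to 1.52 with the cell filter. The mitochondrial genome list stayed within its interval in each alternative. The cause of these moves was not tested. Scaling alternatives shift the genes they keep alike and cannot change a value relative to the all-gene median. Leaving out Scrublet's doublets took away too few barcodes to test the ratios, yet the B/plasma-cell-like name was lost with it.

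The erythroid-like share became 83.4% of Y1, 5.24% of Y2, 90.3% of Y3 and 63.3% of Y4 with the cell filter, under which barcodes of mixed globin and neutrophil RNA in Y1 took an erythroid-like name. It was 98.3% of Y3 and 93.1% of Y4 at resolution 1.0, 86.1% and 84.8% with 20 components and 30 neighbours, and 98.3% and 93.0% with sub-clustering. With the gene filter it was 36.6% of Y1, 99.9% of Y3 and 99.6% of Y4. The Y1 share stayed above that of Y2 and the Y3 share above that of Y4 in each of these.

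In the authors' deposited tables an absolute log2 fold of at least 0.25 left 1297 genes higher in Y2, and 342 higher and 70 lower in Y4; one of at least 0.5 left 385 higher and 25 lower in Y2, and 126 higher and 31 lower in Y4. The Pearson correlation of the ratios was 0.720 at 200 CPM and 0.0396 in erythroid-like clusters, and the Spearman correlation 0.633 at 20 CPM, 0.729 at 200 CPM and 0.427 in erythroid-like clusters. Of values for single genes, 149 stayed within their counting intervals and 42 moved. The 149 include all 20 values under each change of totals or size factors, which cannot move them. All 20 also stayed without Scrublet's doublets. All 20 stayed with the limit of 50 UMIs, but it was not applied to these genes and shifted only the all-gene median. With the mean of per-cell CPM 6 stayed and 14 moved, when thinned 9 and 9, and in erythroid-like clusters only 3 and 11. With the cell filter 15 stayed and 4 moved. Without a low-count filter 16 stayed and 4 moved, again through the all-gene median alone. Adgre1 and Vcam1 for Y4 over Y3 changed sign with the mean of per-cell CPM. Genes with under 10 UMIs under an alternative, such as Kit and Vcam1 in the erythroid-like barcodes of Y1 and Y2, gave no value there. Depth limits Siglec1, Thbs1 in Y3 and Y4, and lists in the 76 erythroid-like barcodes of Y2.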

Other observations

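Gene groups not described in the results are given here, some of them within the range of random lists. Antioxidant enzyme genes had a median relative log2 ratio of -0.29 (-0.92 to -0.05; percentile 1.61) for Y2 over Y1 and -0.69 (-1.56 to 0.00; percentile 2.67) for Y4 over Y3. Gsr, glutathione reductase, was higher in both (0.48 and 0.98), Cat, catalase, was at -1.35 in Y2 over Y1, and Prdx2, an abundant red cell peroxiredoxin, at -1.73 in Y4 over Y3. Genes of the G1/S phase had medians of -0.48 and -0.45, with 23 and 22 of 25 below the all-gene median, at percentiles 0 and 10.4. Within erythroid-like barcodes they were at 0.15 for Y2 over Y1, with 18 of 25 above, and -0.24 for Y4 over Y3. The integrated stress response list was at -0.45 (percentile 0.33) for Y2 over Y1, with Ppp1r15a at -1.18 and Phgdh at 0.62. Mitochondrial biogenesis and dynamics genes lay at 0.11 (percentile 79.1) and 0.26 (percentile 95.0), with Fis1, a fission factor gene, at -0.70 and -1.33 and Tomm20, an import receptor gene of the outer membrane, at 0.39 and 0.58.

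For Y2 over Y1, the early erythroid list was at -0.14 (percentile 21.5), globin at -1.42, glycolysis at -0.08 (percentile 31.1), mitochondrial chaperones and proteases at 0.19 (percentile 93.5), mitochondrial ribosomal proteins at 0.06 (percentile 92.0), stress erythropoiesis at 0.03 (percentile 62.0), apoptosis and p53 targets at 0.13 (percentile 85.6), and CD47 and its partners at -0.10 (percentile 30.3). For Y4 over Y3, the tricarboxylic acid cycle was at 0.14 (percentile 95.0), ribosomal proteins at 0.13 (percentile 99.99), stress erythropoiesis at 0.13 (percentile 73.8), apoptosis and p53 targets at -0.27 (percentile 16.1), and CD47 and its partners at -0.70 (percentile 4.69).

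Markers of other cell types were read in the same way. For Y2 over Y1 the macrophage list was at -0.37 (percentile 3.88), monocytes and dendritic cells at -0.03, B and plasma cells at -1.52, T and NK cells at -0.11, megakaryocytes and platelets at 0.74 with 4 genes measured, mast cells and basophils at -0.61, and stem and progenitor cells at 0.12. With thinning to 2000 UMIs the macrophage list for Y2 over Y1 was at 0.40 and the mast cell and basophil list at 0.90, and the latter was at 0.54 with the mean of per-cell CPM. For Y4 over Y3 these lists were, in the same order, -0.57 (percentile 4.42), 0.16, -3.21, -2.85, -0.94, 3.27 and 1.60, and the stromal and endothelial list, with 3 genes measured, was at 1.11. The megakaryocyte list for Y4 over Y3 turned to 1.52 with the cell filter. Lyz2, a lysozyme gene of macrophages and neutrophils, was at -0.71 in Y2 over Y1 and 1.45 in Y4 over Y3, so that the macrophage list does not single out macrophages.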
